A study of Homo sapiens with 6 samples.

How the data were processed

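Total RNA from 518A2 cells was measured on 6 Affymetrix arrays, 3 after mock transfection and 3 after transfection with SPC2996. Per the labels' protocols, cells were transfected 24 h after seeding, the medium was changed after 4 h, RNA was extracted with Trizol, and biotin-labelled target was made with a whole-transcript sense labelling protocol. The labels disagree on the time of harvest. The sample sources give 24 h, while the treatment protocol gives 3 days of incubation after the change of medium. The time of harvest is therefore open.

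The deposited table holds 1 column per array and 39300 rows. The values are log2 intensities as the authors deposited them, between 0.50 and 13.7. That they are on the log2 scale was read from their range. Per the submitters' processing notes, the affy tool was used. Its version, the background correction, the normalization between arrays, the summarization and the probe set definition are not given in the sources used here. Array medians differed by up to 0.30, so the deposited arrays do not share one distribution at the level of probe sets. The row names are Ensembl gene IDs. No ID occurred more than once, and no row had the same values as another on all arrays. Detection calls were not used here. The number of arrays limits the precision.

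The reference table of 59792 genes that was used for names lists an Ensembl ID for 0 of them, so 0 of the 39300 IDs matched and no probe set is given a gene name. For this reason the level of BCL2 and the 47 gene lists fixed before the data were examined were not analysed here, and no coordinates are given. The rule for named genes, also fixed before the data were examined, was the targeted gene, then the 10 largest rises and falls among genes past the threshold whose groups did not overlap, or the 5 with the lowest unadjusted p in each direction if none passed, then up to 4 members of each gene list. As no gene passed and IDs carry no names, only the 2 IDs with the lowest p in each direction are printed.

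Samples were grouped by their titles. Probe sets were tested if their mean over the 6 arrays reached the 25th percentile of all probe sets, a log2 intensity of 3.14, which kept 29475. The deposited values were used without further normalization. SPC2996 was compared with mock by lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and differences are SPC2996 minus mock on the log2 scale. Single values per array were compared by exact two-sided permutation tests in scipy 1.17.1, which cannot give a p under 0.1 for 3 against 3. Principal components were computed on the tested probe sets, centred and not scaled. Figures were drawn with matplotlib 3.10.9.

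The test was checked on simulated data with the real means and moderated residual variances of the 29475 probe sets, independent errors and 200 changed probe sets in each of 10 simulations. Of changes of 0.5 on the log2 scale 1.4% were recovered, of changes of 1 68.4%, of changes of 1.5 92.8% and of changes of 2 97.2%. False calls were 5.4% of all calls. The simulated errors hold no structure shared between probe sets, such as that of the first principal component, so recovery on the real arrays can differ. Moderated variances spread less than real ones, and most planted changes were of 1 or more, which eases the adjusted threshold. On the real arrays a difference of -1.40, for ENSG00000140465, had a limma adjusted p of 0.236. The simulated shares may thus overstate recovery.

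The titles number the replicates 1 to 3 in both groups, and nothing in the labels says that a number marks a shared day or batch. Alternatives fixed before the data were examined were no filter, a filter at the 50th percentile, quantile normalization, centring on array medians, an intensity trend with robust variances, array weights, the replicate number as a block, stricter thresholds and leaving out each array in turn. Cyclic loess normalization, the array median as a covariate, leaving out both ends of the first component, and the trend with the stricter filter were chosen after seeing the data. The labels give no scan date, slide or batch.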

Results

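The study asked which transcripts differ in level after an antisense oligonucleotide, SPC2996, is delivered into 518A2 cells, a human melanoma cell line. SPC2996 is a locked nucleic acid oligonucleotide that was designed against the messenger RNA of BCL2, a protein that protects cells from apoptosis. Per the labels, transfection was with lipofectamine at 5 µg/ml for 4 h in both groups. The treated group received the oligonucleotide at 10 nM, and the control group was mock-transfected. No group received a control oligonucleotide, so an effect of targeting BCL2 and one of delivering any oligonucleotide cannot be told apart. Each group held 3 arrays, which the labels name as biological replicates. Biotin-labelled whole-transcript target from total RNA was hybridised to each array, and the values analysed were log2 intensities of 39300 gene-level probe sets, each identified by an Ensembl gene ID. The files do not pair these IDs with gene names, so probe sets are reported by ID, and the level of the targeted gene was not analysed here. The check of the labels that a lower target level would give was therefore not made.

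The 6 arrays had similar intensity distributions, with medians between 4.49 and 4.79. This range is not small beside the median absolute difference between groups, 0.18 over the probe sets tested. The median log2 intensity was 4.79, 4.64 and 4.66 in mock replicates 1, 2 and 3, and 4.49, 4.56 and 4.69 in SPC2996 replicates 1, 2 and 3. The group means of these medians were 4.70 ± 0.08 in mock and 4.58 ± 0.10 in SPC2996 (SD, n = 3 each). Their difference did not pass an exact two-sided permutation test (p = 0.3), in which 3 arrays against 3 cannot give a p below 0.1. The standard deviation of log2 intensity over all probe sets was 1.87 ± 0.02 in mock and 1.92 ± 0.03 in SPC2996 (SD, n = 3 each, exact permutation p = 0.2). Across the 29475 probe sets kept for testing, Pearson's r averaged 0.965 over the 3 pairs of mock arrays, 0.970 over the 3 pairs of SPC2996 arrays and 0.963 over the 9 pairs of unlike arrays. These correlations are across probe sets, which are not independent replicates. The lowest, 0.936, was between mock replicate 1 and SPC2996 replicate 1.

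The first principal component did not part the groups. It carried 44.3% of the variance, and the second carried 16.5%. Mock replicate 1 scored -47.4 and SPC2996 replicate 1 scored 49.6, at opposite ends. Mock replicates 2 and 3 scored -5.90 and -6.14. SPC2996 replicate 2 scored 22.5, and SPC2996 replicate 3 scored -12.6, within the range of the mock arrays. The group means were -19.8 ± 23.9 in mock and 19.8 ± 31.2 in SPC2996 (SD, n = 3 each, exact permutation p = 0.3).

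**Figure D1:**
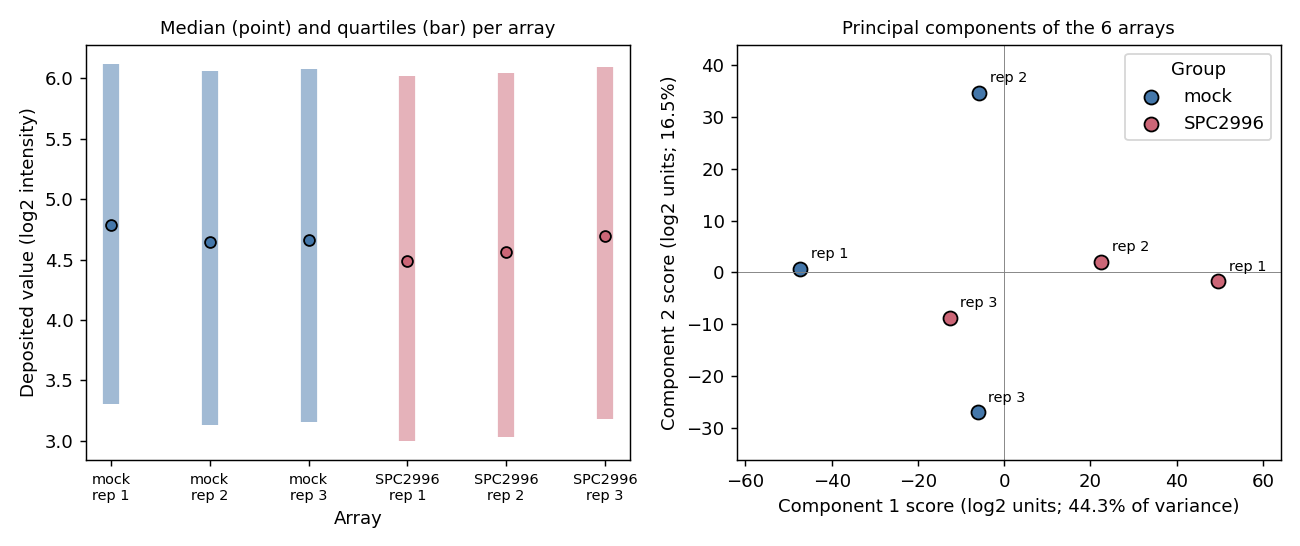
The left panel plots each array's median (point) and quartiles (bar) of the deposited log2 intensities, and the right panel plots the scores of the 6 arrays on the first 2 principal components in log2 units. Medians lie between 4.49 and 4.79, and SPC2996 replicate 3, at -12.6 on component 1, lies among the mock arrays.

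No probe set differed between SPC2996 and mock at an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment over 29475 probe sets. The lowest adjusted p was 0.236, and 2 probe sets lay under 0.25. At an unadjusted p under 0.05 there were 3222 probe sets, 1494 higher and 1728 lower in SPC2996, where 1474 would be given by chance if no level differed and errors were independent. At an unadjusted p under 0.001 there were 67, against 29.5 by chance. This count lay near the chance number when 1 array was left out, at 35 without mock replicate 1, 30 without mock replicate 2, 32 without SPC2996 replicate 1 and 27 without SPC2996 replicate 2. It was 50 without mock replicate 3, 96 without SPC2996 replicate 3, 29 with the replicate number as a block and 504 with array weights. A fit with fewer arrays or with the block has less power, so its count can fall towards chance also where levels differ. The lower counts therefore cannot decide whether the excess is chance or rests on single arrays. The count of 3222 moved by over 1.5 times when single arrays were left out. It was 1796 without mock replicate 1, 1794 without SPC2996 replicate 1, 1698 without SPC2996 replicate 2 and 6084 without SPC2996 replicate 3. No probe set passed the adjusted threshold in any of these 4 fits, nor without mock replicate 2 or 3. Array weights in limma were the only planned setting with calls, 2 probe sets higher and 6 lower in SPC2996.

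The differences were small for most probe sets. The median absolute difference was 0.18 on the log2 scale and the 95th percentile was 0.54, beside a median standard error of 0.15. There were 109 probe sets with a 2-fold or larger difference, 32 higher and 77 lower in SPC2996. Of these, 29 of the higher and 68 of the lower had an unadjusted p under 0.05. The count was 152 without mock replicate 1, 210 without mock replicate 2 and 242 without mock replicate 3. It was 120 without SPC2996 replicate 1, 166 without SPC2996 replicate 2 and 270 without SPC2996 replicate 3. It also depended on the filter on dim probe sets, with 202 when none was set and 25 with the stricter one. It was 304 with array weights, 171 with the array median as a covariate and 181 without mock replicate 1 and SPC2996 replicate 1 together. All 3 SPC2996 values lay outside the range of the 3 mock values for 5410 probe sets (18.4%), where chance gives 10%. Of these, 2433 were higher and 2977 lower in SPC2996. With 1 array left out chance gives 20%, and the share was 23.3% without mock replicate 1, 31.7% without mock replicate 2 and 31.0% without mock replicate 3. It was 23.3%, 22.9% and 47.6% without SPC2996 replicates 1, 2 and 3. Without mock replicate 1 and SPC2996 replicate 1 together, a setting chosen after seeing the data, the share was 32.7% where chance gives 33.3%, and 1561 probe sets had an unadjusted p under 0.05 where chance gives 1474. These arrays lay farthest apart on component 1, so leaving them out favours a smaller excess, and fewer arrays give less power. This setting therefore cannot decide whether the excess rests on them alone.

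The split between higher and lower levels depended on how the arrays were scaled to one another, on the filter on dim probe sets and on the variance model. On the values as deposited, 46.4% of the 3222 probe sets at an unadjusted p under 0.05 were higher in SPC2996, and the median difference over all probe sets tested was -0.08. With each array centred on its own median, 65.7% of 3096 were higher and the median difference was 0.01. With quantile normalization, 56.3% of 3016 were higher and the median difference was -0.01. The larger number of lower probe sets among those with a 2-fold difference, 77 against 32, did not hold under these scalings, with 58 higher and 47 lower after centring and 50 higher and 42 lower after quantile normalization. The same was true of the probe sets whose groups did not overlap, with 2830 higher and 2198 lower after centring and 2625 higher and 2477 lower after quantile normalization. On the deposited scale with the stricter filter, 56.7% of 2642 probe sets at an unadjusted p under 0.05 were higher, with 14 higher and 11 lower at 2-fold, and 2150 higher and 1824 lower among those whose groups did not overlap. With an intensity trend and robust variances on the deposited values, 51.9% of 3388 were higher. Other settings on the deposited scale went the other way. The share was 40.6% of 3711 with no filter, 38.7% of 8557 with array weights and 39.8% of 1889 with the replicate block. At 2-fold, 52 were higher and 150 lower with no filter, and 96 higher and 208 lower with array weights. Leaving out 1 array gave from 36.3% without SPC2996 replicate 3 to 46.8% without mock replicate 1. The deposited differences also varied with brightness. When the probe sets tested were cut into 10 classes of equal size by mean intensity, the median difference was -0.12 in the dimmest class and 0.10 in the brightest. A value per array for this shift, the brightest class minus the middle classes, did not pass an exact permutation test between groups (p = 0.3).

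The probe sets with the lowest p in each direction showed differences of over 2-fold, larger than the spread between replicates. ENSG00000140465 was lower in SPC2996, at 5.56 ± 0.11 against 6.96 ± 0.12 in mock (log2 intensity, SD, n = 3 each). Its difference was -1.40 with a 95% interval from -1.68 to -1.12, and limma's adjusted p was 0.236. ENSG00000135114 was lower as well, at 5.68 ± 0.15 against 6.97 ± 0.09 in mock (SD, n = 3 each). Its difference was -1.29, with an interval from -1.58 to -1.001 and a limma adjusted p of 0.244. ENSG00000148677 was higher in SPC2996, at 8.42 ± 0.08 against 7.03 ± 0.24 in mock (SD, n = 3 each). Its difference was 1.38, with an interval from 1.04 to 1.73 and a limma adjusted p of 0.26. ENSG00000131914 was higher at 7.79 ± 0.17 against 6.68 ± 0.15 in mock (SD, n = 3 each). Its difference was 1.12, with an interval from 0.79 to 1.44 and a limma adjusted p of 0.346. These intervals are not adjusted for the number of probe sets, and the 4 were picked for their low p among 29475, a choice that favours overstated differences.

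**Figure D2:**
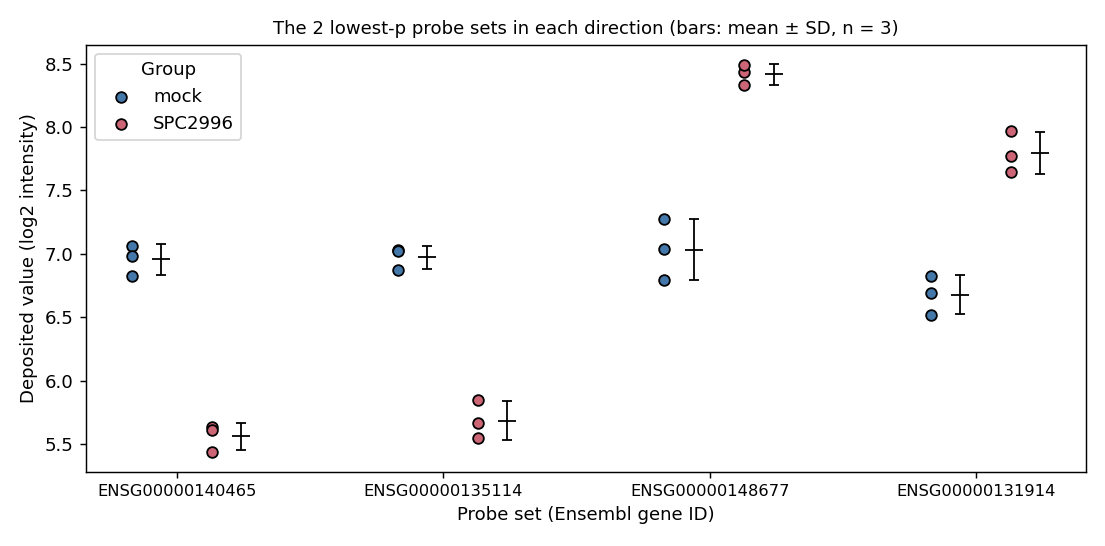
Deposited log2 intensities of the 2 probe sets with the lowest p in each direction, with one point per array and the mean ± SD of each group (n = 3) beside the points. The 3 SPC2996 values of ENSG00000140465 lie between 5.44 and 5.63, below the mock values from 6.82 to 7.06, and those of ENSG00000148677 lie between 8.33 and 8.49, above the mock values from 6.79 to 7.27.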

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

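The absence of calls held under all planned settings except array weights, which called 8 probe sets, 2 higher and 6 lower in SPC2996. All 8 were among the 20 with the lowest p in the unweighted fit, and 3 of the 4 named probe sets were among them. The weight estimation stopped before it converged and gave SPC2996 replicate 2 a weight of 6.57 against 0.431 for SPC2996 replicate 3. Of the settings chosen after seeing the data, the intensity trend with the stricter filter called 3 and the others called 0. The stricter thresholds on the same fit could give no more than 0 and add nothing. The lowest adjusted p ranged from 0.018 to 0.748 over the 17 refits. Leaving out each array in turn gave from 0 to 0 calls, and from 1698 to 6084 probe sets at an unadjusted p under 0.05, against 3222. That count was 8557 with array weights, 1889 with the replicate block and 1561 without both ends of the first component. It stayed within 1.5 times of 3222 in the other settings, and the cause of the moves was not tested. The labels give the replicate numbers no further meaning. Deviations from the group means correlated at -0.34, 0.06 and -0.17 between arrays numbered 1, 2 and 3. No mock array and 1 SPC2996 array correlated best with its own number. With so few arrays these correlations cannot decide whether arrays with the same number shared a day or batch. The fit with the block gave 0 calls, as did the fit without it, which says nothing about pairing. The 4 named differences kept their sign in all 17 refits, between -1.52 and -1.31 for ENSG00000140465, -1.37 and -1.20 for ENSG00000135114, 1.254 and 1.502 for ENSG00000148677, and 1.002 and 1.207 for ENSG00000131914. The first 3 of these each passed the threshold in 2 refits and the last in 0. The 4 were picked for low p in the same arrays, and several refits leave the difference itself unchanged by construction. Their constant sign is therefore no independent support. Averaging probe sets of one gene was not run, since each ID has 1 probe set. The tests of BCL2 and of the gene lists, with their alternatives, were not run, since no names were matched.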

Other observations

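The tests in this part were chosen after the data were first examined, and for the label of SPC2996 replicate 3 and for brightness after quantile normalization the criteria were set before the outcome was seen.

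The largest structure in these arrays is an axis on which the groups overlap. Component 1 followed the array median across the 6 arrays (Pearson's r = -0.995, exact permutation p = 0.0028; Spearman's rho = -1.0, exact permutation p = 0.0028; Benjamini-Hochberg adjusted p = 0.011 for each over 4 relations). Without the 2 arrays farthest from the middle, r was -0.979 over 4 arrays. Component 1 and the medians are computed from the same intensities. An offset shared by most probe sets thus enters component 1 by construction, and these p-values give no independent support. The 4 relations, of the median and standard deviation to component 1 before and after quantile normalization, overlap. The weakest was that of the standard deviation before it (Spearman's rho = 0.83, exact permutation p = 0.058). The values argue against unequal array-wide distributions alone as its source: after quantile normalization component 1 still carried 2.20 times the share of component 2. Its scores then correlated at 0.999 with those before. They also still followed the deposited array median (Pearson's r = -0.991) and standard deviation (r = 0.981). Quantile normalization cannot remove effects on single probe sets that travel with array intensity, so such effects stay open as a source of component 1. Treatment as its source stays open: the lowest SPC2996 score lay 6.74 units below the highest mock score, a gap that rests on SPC2996 replicate 3 and is smaller than the spread within groups. A wrong label on SPC2996 replicate 3 stays open as well: over the 100 probe sets that best separated the other 5 arrays, its median position was 0.464, where 0 is the mock mean and 1 the mean of the other SPC2996 arrays, while the other 2 SPC2996 arrays, each left out in turn, lay at 0.723 and 0.721 and the mock arrays at 0.256, 0.441 and 0.548. A weaker response or lower uptake in that culture, and RNA quality or amount, were not tested and may contribute as well.

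Other splits of the arrays give a limited reference for the excess of low p-values. The real split gave 3222 probe sets at an unadjusted p under 0.05, and 3 of the 10 splits, the real one included, gave as many. The highest other, 4762, set mock replicates 1 and 3 with SPC2996 replicate 3 against the rest, and a further split with mock replicates 1 and 2 beside SPC2996 replicate 3 gave 3391. The first of these splits follows the order of the arrays on component 1. At an unadjusted p under 0.001 the real split gave 67, the highest of the 10, and the highest other gave 64. The count of 67 was between 27 and 96 when 1 array was left out. At the adjusted threshold all 10 splits gave 0 genes, so the highest other was 0 too. With 10 splits no share under 0.05 can be reached. Every other split also sets 2 arrays of 1 treatment with 1 of the other, so none is free of treatment. The splits with 4762 and 3391 both keep SPC2996 replicates 1 and 2 together, so they could carry part of a treatment effect. Their counts therefore cannot decide whether the excess of the real split is due to treatment. After quantile normalization the real split gave 3016 and 59, against up to 3927 and 49 in the others.

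The shift by brightness, from lower levels in SPC2996 among dim probe sets to higher levels among bright ones, was weighed against the normalization of the deposited values and against treatment. The medians of the 10 brightness classes spanned 0.23 as deposited and 0.040 after quantile normalization. The span after quantile normalization met the criterion set beforehand for the normalization of the deposited values as the source. That criterion was not used to decide, because quantile normalization removes almost any such shift, whatever its source. The normalization of the deposited values and a broad change in the cells therefore cannot be told apart by it. Treatment stays open as well: the bright minus middle difference of SPC2996 replicate 3 lay 0.023 below the highest mock value, which is smaller than the spread within groups (SD 0.131 in mock and 0.155 in SPC2996, n = 3 each). The group means were -0.107 in mock and 0.104 in SPC2996 (exact permutation p = 0.3). This measure ranked the arrays in the same order as component 1, from mock replicate 1 (-0.259) to SPC2996 replicate 1 (0.258). The shift and component 1 therefore cannot be told apart here.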
